A study of Mus musculus with 2 samples.

How the data were processed

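Gene expression was measured by RNA sequencing in mouse heart tissue, kept in a preservative for RNA and frozen, from animals labelled as having had a high-fat diet (HFD) and myocardial infarction (MI), the expansion of MI being taken from the series title. The labels give 2 libraries, 1 from heart tissue treated with probucol and 1 from untreated heart tissue. Both have the age label day 14, which does not say from which event the days were counted. The groups were taken from the treatment label of each sample. Per the labels' protocols, total RNA was extracted with a miRNeasy kit and libraries were made with a TruSeq stranded mRNA kit. Whether each library came from 1 animal or a pool, and which part of the heart was taken, is not given in the sources used here. The labels do not state the genotype of the animals either; a mark in the names of the deposited files, which could refer to a lipoprotein genotype, is not explained there and was not interpreted.

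The values deposited by the authors are FPKM, fragments per kilobase of transcript scaled to the number of mapped fragments, with 1 value for each of 24346 gene symbols per library. The submitters' processing notes name TopHat2 2.1.1, Bowtie2, Cuffdiff 2.2.1 and the mouse build mm10. The roles and order of these tools, the gene annotation and the scaling between libraries are not given in the sources used here. Both libraries list the same symbols, with 0 duplicated symbols. FPKM depends on what else was sequenced in a library, so a few abundant transcripts that take a larger share lower the values of all other genes. For genes shorter than a sequenced fragment the effective length approaches 0, and FPKM can become very large or be listed at 0.

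The unit was tested on the low values. Among 1313 genes that were low in both libraries, 300 had, within 0.3%, the ratio 1.12 between libraries that is given by equal fragment numbers. Over genes with 1 transcript, and with 210 bases subtracted from the transcript length, 1 fragment in a transcript of 1 kb effective length was worth 0.149 FPKM in the probucol library and 0.134 FPKM in the untreated library. Put the other way, 1 FPKM in such a transcript stands for 6.70 and 7.47 fragments. Fragment numbers of selected genes with 1 transcript were recovered from these steps. Estimates were rounded to whole fragments, which checks the recovery only for the smallest numbers. Intervals of their ratios are exact binomial 95% intervals (Clopper-Pearson). Such intervals cover counting error only, since amplified fragments are not independent molecules. A count of 0 allows up to 3 fragments.

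With 1 library per group there is no test between the treatments, and no p-value, SE or SD across libraries is given. Every statement describes these libraries, not the conditions. The difference of each gene was taken as log2((FPKM probucol + 0.5)/(FPKM untreated + 0.5)), without rescaling, for the 12882 genes with a mean FPKM of at least 0.5. Every log2 ratio and fold below is on this scale, which understates the difference of low genes. Genes at least 2-fold higher or lower were counted.

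Lists of genes, 60 in all, were fixed for the cell types, pathways and stress responses that heart tissue, infarction and the drug concern, and for tissues that could be mixed in. For each list the median log2 ratio of its measured members (those past the filter) was placed among the medians of 10000 random lists of the same size, matched on mean FPKM in 20 bins. A list with at least 4 measured members was said to stand apart in the lowest or the highest 2.5% of the random medians. Members at least 1.5-fold higher or lower were counted. The percentile treats genes as exchangeable, and members of a list are correlated, so it is a description and not a probability.

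The genes named were chosen by rule. First came the 12 highest and the 12 lowest log2 ratios among genes with at least 5 FPKM in the higher library, leaving out 278 predicted genes, rows of several genes and immunoglobulin or T cell receptor segments. Of each list that stood apart, up to 4 members furthest in the list's direction could be named, and of other lists up to 2 members with the largest ratio in either direction. Further, 25 genes of the study's subject were to be named whatever their values. Some genes that the rule takes are not reported here. The lists, the rule, the filter, the pseudocount and the limits were set before the data were examined. Where other genes are named, they were chosen after their values were seen.

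The procedure was tested on simulated libraries with the FPKM and depth of the comparison of probucol with untreated. Of 100 genes changed 4-fold, 100% passed the 2-fold limit in the right direction. Of 100 genes changed 2-fold, 46% passed the 2-fold limit and 97% the 1.5-fold limit. Of 12688 unchanged genes, 0.102% passed the 2-fold limit by counting error alone, and 3 of 100 lists without a shift stood apart. The simulation gave all genes the same transcript length, and the changed genes were drawn from those well above the filter. Its shares were therefore not shown to hold for short genes or for genes near the filter. The simulation holds no differences between animals.

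Alternatives were a pseudocount of 0.1 or 1, no filter or a mean of at least 1 or 5 FPKM, limits of 1.5-fold and 3-fold, and 4 other scalings. These scalings were rescaling to a common sum (TPM), a median ratio of 0, equal upper quartiles, and rescaling without the 50 most abundant genes. For lists, random lists matched in 10 bins or not matched, the mean in place of the median and each member left out in turn were also tried. Restricting the comparison to protein-coding genes, for the counts, the lists, the mean of list members and the choice of named genes, was added after seeing the data. Rescaling to TPM moved the median log2 ratio of all genes from 0.01 to -0.13, so values lie lower under that scaling, by amounts that differ between genes because of the pseudocount.

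Gene types, transcript lengths and coordinates come from RefSeq (GRCm38.p6) and transcript models of GENCODE release M21, both on the build of mm10. Of the symbols, 24242 matched RefSeq and 20501 of them are protein-coding. Near-identical copies share reads, and how the authors' counting divided them is not given, so such genes are reported as uncertain. Immunoglobulin constant genes and mitochondrially encoded genes were not analysed here. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.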

Results

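RNA sequencing was compared between 2 libraries of mouse heart tissue from a model of high-fat diet and myocardial infarction, both with the age label day 14. The treated sample had received probucol, an antioxidant drug that lowers cholesterol, and the other was untreated. Each group has 1 library, so no difference below has a replicate check. The study's title concerns XCR1+ dendritic cells, the activation of CD4+ T helper 1 (Th1) cells and remodelling of the heart after infarction. The comparison therefore addresses how transcripts of these cells, and of inflammation, scar and heart muscle, differed between treated and untreated heart tissue. By the steps of low values, 1 FPKM in a transcript of 1 kb effective length stands for 6.70 fragments in the probucol library and 7.47 in the untreated library, so their depths were similar. FPKM of at least 0.5 were listed for 12657 and 12941 genes. The 10 most abundant genes held 17.2% of all FPKM in the probucol library and 14.4% in the untreated library.

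Inflammatory, proliferative and scar transcripts were lower in the probucol library, and transcripts of heart muscle and its energy metabolism were moderately higher. Among 12882 measured genes, 662 were at least 2-fold lower and 138 at least 2-fold higher with probucol. Fragment numbers could be estimated for 419 of the lower and 76 of the higher genes. Of these, 378 and 51 had at least 20 fragments in both libraries together, so the higher genes rest more often on few fragments. Of protein-coding genes, a restriction chosen after the data were seen, 611 were lower and 95 higher. Of 50 lists with enough measured members, 30 stood apart as lower and 8 as higher, where 2.5 would be expected by chance for independent genes. The log2 values of the libraries correlated across genes with Pearson's r = 0.953 and Spearman's rho = 0.958, and genes are not independent replicates.

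The lowest protein-coding genes in the probucol library included several products of macrophages and stressed tissue. Spp1, which encodes the secreted protein osteopontin (chromosome 5, 104435111 to 104441053, GRCm38/mm10), had 14.2 FPKM with probucol and 201 without, a log2 ratio of -3.78. Hmox1, the inducible heme oxygenase (chromosome 8, 75093618 to 75100593), had 14.0 against 112 FPKM, 7.78-fold lower. Timp1, an inhibitor of matrix metalloproteinases (chromosome X, 20870166 to 20874737), had 23.8 against 169 FPKM, 6.98-fold lower. Their depth was ample: Hmox1 had 127 against 1139 fragments, with a ratio between 0.103 and 0.150, and Timp1 had 107 against 849. Also among the lowest were Wfdc17 (log2 ratio -3.09), Nmrk2 (-3.08), a kinase of nicotinamide riboside, and Sprr1a (-2.86). The chemokine Ccl8 (-2.77), the scavenger receptor Marco (-2.81), the macrophage product Cd5l (-2.74) and the lipid receptor Trem2 (-2.53) completed this group. The remaining members of the lowest 12, Amd1 and H2-Q8, have near-identical copies and are treated separately below.

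The highest protein-coding genes in the probucol library were fewer and more varied. Gp9, a platelet glycoprotein, had 7.93 FPKM against 0.444, and Nrgn, which encodes neurogranin, had 16.0 against 1.36. Ppbp, which encodes the platelet basic protein, had a log2 ratio of 2.07. The inducible heat shock genes Hspa1b (2.36) and Hspa1a (2.18), which share nearly all their coding sequence, were both higher. Timp4, a metalloproteinase inhibitor of heart muscle, had 58.0 against 16.3 FPKM, 3.48-fold higher and opposite to Timp1. Lrrc4b (2.05), the cell cycle inhibitor Cdkn1c (1.71), the phosphodiesterase Gdpd3 (1.70) and Pxmp2 (1.48), a peroxisomal membrane protein, followed.

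**Figure D1:**
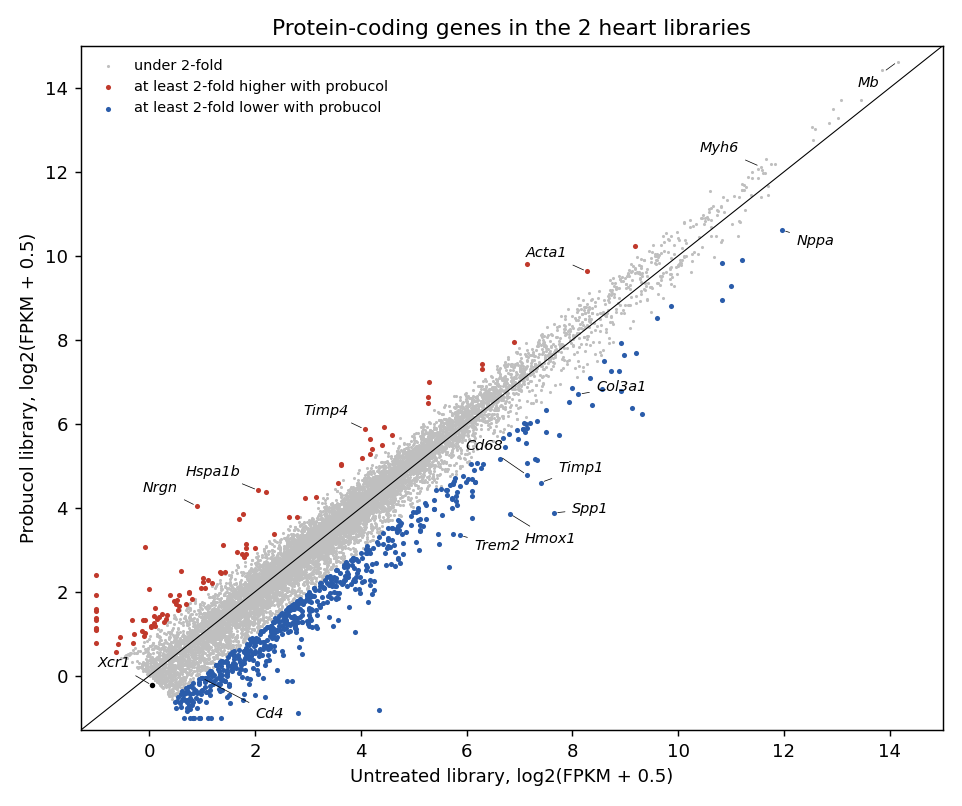
Protein-coding genes with a mean FPKM of at least 0.5, untreated library on the x axis and probucol library on the y axis, both as log2(FPKM + 0.5); each point is 1 gene, the line marks equal values, and Xcr1 is added in black although it lies under the filter. The 611 genes at least 2-fold lower with probucol (blue) outnumber the 95 at least 2-fold higher (red).

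Several genes at the extremes share reads with a near-identical copy and are uncertain. Amd1 had 0.0708 FPKM with probucol and 19.7 without, but the sum of Amd1 and Amd2 was 68.4 against 66.6, a log2 ratio of 0.04. Rps27 had a log2 ratio of 2.67, yet the sum of Rps27 and Rps27rt had -0.13. H2-Q6 was higher (1.91) and H2-Q8 lower (-3.70), while the sum of H2-Q6, H2-Q7, H2-Q8 and H2-Q9 had -0.84. Atp6v0c-ps2 was listed at 0.0358 FPKM against 118, while with its parent gene Atp6v0c the sum had -0.09.

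When all gene types were ranked, as the rule set beforehand requires, the extremes were taken up by short RNAs. The 12 highest were Mir208b, Mir1901, Mir678, Mir135a-1, Mir8116, Snora68, Mir1291, Mir1957b, Snora26, Snord17, Rpph1 and Vaultrc5, each listed at 0 in the untreated library. Of the 12 lowest, Mir762, Mir130c, Mir147, Mir1905, Mir3074-1, Mir719, Mir8097, Mir8108, Mir8094, Snora64 and Snora16a were listed at 0 in the probucol library, and Atp6v0c-ps2 was the remaining member. No fold is given for these genes, since a value of 0 in a file of FPKM can be a failed estimate.

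Macrophage transcripts were lower throughout. All 15 macrophage markers were at least 1.5-fold lower in the probucol library, with a median log2 ratio of -1.50 that lay below all 10000 random lists. Cd68, a lysosomal protein of macrophages (chromosome 11, 69664213 to 69666170), had 27.0 against 140 FPKM. Fcgr1 (-1.99), an Fc receptor, Lyz2 (-1.88), the lysozyme of myeloid cells, and Ms4a7 (-1.83) were close behind. Of 11 genes of lipid-associated macrophages, 9 were lower by this limit, with a median of -1.14. After Spp1 and Trem2, the lowest were Gpnmb (-2.33) and Lgals3 (-2.02), the gene of galectin-3. Lpl, the lipase that releases fatty acids from lipoproteins and that heart muscle also makes, was the 1 member above 0, at 0.53, and Cd9 had -0.33. Scavenger receptors had a median of -1.16, with 6 of 9 lower, among them Marco, Cd68 and Msr1 (-1.89). Scarb1, the receptor for high-density lipoprotein, had 0.904 against 1.10 FPKM and Cd36 had 0.37. Apoe, the apolipoprotein of macrophages and liver, had 179 against 389 FPKM. The labels do not state the genotype, so an altered lipoprotein gene in both groups is not excluded, which limits what the values of Apoe and Scarb1 mean.

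Transcripts of monocytes, chemokines and innate immunity were lower as well. Of 8 monocyte markers, 7 were at least 1.5-fold lower (median -1.02), including Plac8 (-1.82), Chil3 (-1.31) and Ccr2 (-1.25), the receptor that draws monocytes into tissue. Of 19 chemokines, 13 were lower and 0 higher by this limit (median -1.14), with Ccl6 at -2.13, Ccl3 at -1.87 and Ccl2, the main ligand of Ccr2, at -1.73. All 8 measured inflammatory cytokines and inflammasome genes were lower (median -0.99), including Il18 (-1.63) and Il1rn (-1.52), the interleukin 1 receptor antagonist. Complement genes had a median of -1.15 with 8 of 11 lower, led by C3ar1 (-2.02) and Cfp (-1.74). Cathepsins and cystatins had a median of -0.98 with 7 of 10 lower, led by Ctss (-2.16), a cathepsin of antigen-presenting cells, but by the mean of members over all genes this list lay at percentile 3.46 and did not stand apart. Type I interferon response genes had a median of -0.95 with 13 of 16 lower, among them Oas1a (-1.45) and Irf7 (-1.36).

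Cell cycle genes were lower, with a median close to that of macrophage markers. Of 14 members, 13 were at least 1.5-fold lower, with a median of -1.49 below all random lists. Ccna2 (-1.78), Birc5 (-1.72), Cdk1 (-1.62) and Top2a (-1.61) were the lowest. Mki67, a general marker of proliferating cells that was chosen after its value was seen, had 88 against 352 fragments.

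For XCR1+ dendritic cells, the subject of the study's title, the markers were slightly lower, and Xcr1 itself was low, with a mean under the filter. Xcr1 itself (chromosome 9, 123852315 to 123862029), the receptor of the chemokine Xcl1, had 0.352 FPKM with probucol and 0.536 without. These values correspond to 10 and 17 fragments, with a ratio between 0.269 and 1.52, so no difference was detectable at this depth. Clec9a, a receptor for dead cells on the same dendritic cells (chromosome 6, 129408862 to 129424764), had 1.96 against 2.05 FPKM. Xcl1 had 1.02 against 2.73 FPKM, which rest on 2 and 6 fragments. The 9 measured markers of conventional type 1 dendritic cells (cDC1) had a median of -0.46 at percentile 1.88, with 4 at least 1.5-fold lower and 0 higher. The lowest were Irf8 (-1.38), Cadm1 (-1.14) and Batf3 (-0.94); Irf8 and Cadm1 are also expressed outside these cells. This list no longer stood apart under 6 alternatives, with percentiles from 3.60 to 7.94. Type 2 conventional and mature dendritic cell genes were lower, with a median of -0.75 and 6 of 10 past 1.5-fold. The lowest were Itgax (-1.41), Cd80 (-1.34) and Sirpa (-1.05). Members differed, with Ccl17 at -0.09 and 1 of the 10, Cd209a, above 0 at 0.53. Which cells the lower members came from was not tested. Il12b, a subunit of the cytokine that induces Th1 cells, was listed at 0 with probucol and 0.0583 FPKM without. The latter value rests on 1 fragment, rounded from 0.72, so no difference can be read from it.

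Antigen presentation genes were lower by less than macrophage markers. H2-Aa, a class II histocompatibility chain, had 248 against 336 FPKM, and Cd74, the class II invariant chain, had 306 against 395 FPKM. The 9 measured class II genes had a median of -0.37 at percentile 1.59, with 2 past 1.5-fold, H2-DMb2 (-1.35) and H2-Oa (-0.60). Without its lowest-expressed member the class II list did not stand apart, with a median of -0.29 at percentile 3.43 among genes of at least 1 FPKM. Class I genes had a median of -0.57, with 12 of 12 below 0 and 6 past 1.5-fold, among them Nlrc5 (-0.91), the activator of class I genes, and H2-D1 (-0.85). By the mean of members over all genes the class I list lay at percentile 3.58 and did not stand apart.

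T cell transcripts were too scarce for most comparisons. Cd4, the co-receptor of helper T cells that some macrophages also carry, had 0.466 FPKM with probucol and 1.48 without, from 9 against 32 fragments, with a ratio between 0.132 and 0.673. Cd3e, a chain of the T cell receptor complex, had 4 fragments with probucol and 0 without. Cd3d, Cd3e and Cd3g together had 5 against 7 fragments, with those of Cd3d rounded from 1.25 and 3.76, and a ratio between 0.199 and 2.92, so neither a 2-fold lower nor a 2-fold higher level is excluded. Cd8a had 0.103 against 0.185 FPKM. Of 16 T cell markers, 3 passed the filter, and their median of -0.02 was not called. Tbx21, the transcription factor of Th1 cells, had 1 against 3 fragments (0.0637 and 0.171 FPKM), and Ifng, their main cytokine, was listed at 0 in both libraries. Of 12 Th1 genes, 2 passed the filter, too few for a call. Of these 2, 1 lay above 0 (Il12rb2, 1.09 against 0.831 FPKM) and 1 below. From the list, 2 receptors of Th1 cells were chosen after their values were seen. Cxcr3 had 1 against 10 fragments, with a ratio between 0.00257 and 0.784. Cxcr6 had 1 against 6, with a ratio between 0.00404 and 1.53 that includes no difference. Il2 (0.202 against 0 FPKM) and Fasl (0.0889 against 0) went the other way. Picked for their values from 12 genes, the 2 receptors do not stand for the list.

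Genes of other T cell subsets were likewise sparse. Gata3, the factor of type 2 helper cells, had 7 against 5 fragments (0.348 and 0.223 FPKM), and Foxp3, that of regulatory T cells, was listed at 0 in both. Type 2 helper genes (3 measured, mean -0.88), type 17 genes (2 measured, mean 0.28) and regulatory T cell genes (2 measured, mean -0.26) were too few to be called. The interferon-gamma response list, genes that this cytokine induces in many cell types, had a median of -0.40 at percentile 0.29, with 6 of 15 at least 1.5-fold lower and 0 higher. Its lowest members were the chemokines Cxcl10 (-1.46) and Cxcl9 (-1.10), then Gbp3 (-0.97), while Irf1 had 0.01. Natural killer and cytotoxic genes had a median of -1.10, with 5 of 6 lower, including Ncr1 (-1.43) and Gzmb, which had 2 against 10 fragments with a ratio between 0.0238 and 1.05, a range that includes no difference. Only 3 of these genes had a mean of at least 1 FPKM, too few for a call at that filter.

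**Figure D2:**
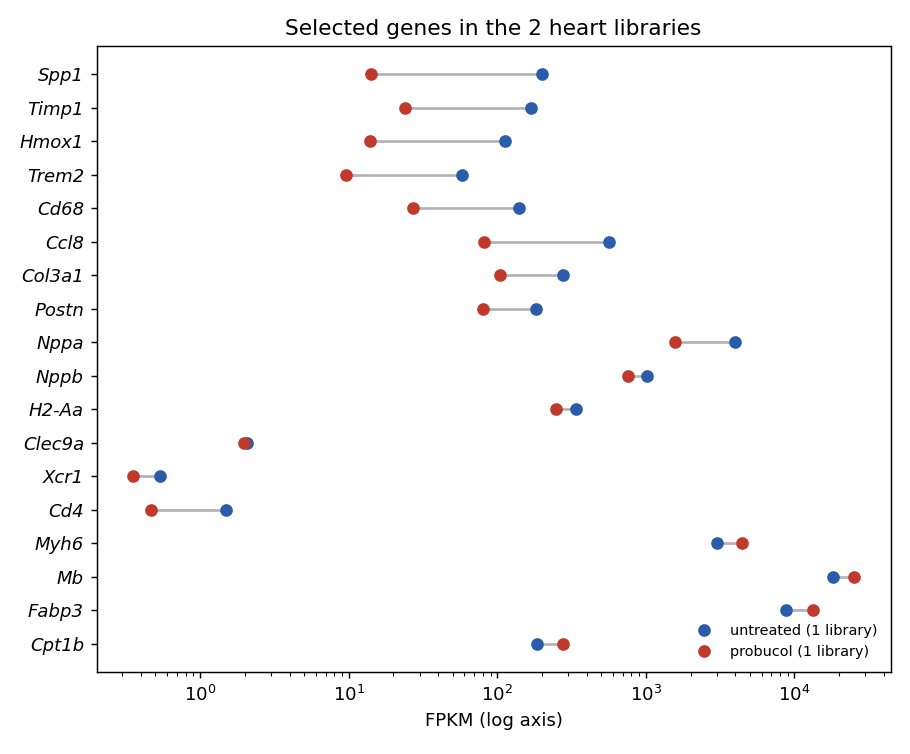
FPKM of 18 genes of inflammation, scar, dendritic cells, T cells and heart muscle, on a log axis, with 1 point per library (untreated blue, probucol red). Spp1, from 201 to 14.2 FPKM, shows the widest gap, and the points of Clec9a nearly coincide.

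Transcripts of scar matrix were lower in the probucol library. Of 24 measured matrix genes, 19 were at least 1.5-fold lower and 0 higher, with a median of -0.98 below all random lists. Col3a1, the chain of type III collagen (chromosome 1, 45311538 to 45349706), had 104 against 277 FPKM, and Col1a1, of type I collagen, had 33.5 against 63.4. Postn, the gene of periostin from activated fibroblasts, had 79.5 against 181 FPKM. Tenascin C (Tnc, -1.75), Thbs4 (-1.57), Cthrc1 (-1.48) and Thbs1 (-1.45) were the lowest of the list. Matrix proteases and their inhibitors had a median of -0.71, with 8 of 15 lower, including the macrophage elastase Mmp12 (-2.36), Mmp3 (-2.25) and Mmp13 (-1.55); Timp4 was the 1 member past the limit in the other direction. Fibroblast markers were lower by less, with a median of -0.47 and 5 of 13 past 1.5-fold, led by Mfap5 (-0.85) and Thy1 (-0.83). Genes of TGF-beta signalling had a median of -0.36, with Inhba at -1.61. Basement membrane genes had a median of -0.33, with 2 of 13 lower and 1 higher, Lama5 (0.62). By the mean of members over all genes, fibroblast markers (percentile 3.45) and basement membrane genes (4.11) did not stand apart.

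Heart muscle transcripts were higher by a small and even amount. All 20 cardiomyocyte structural genes lay above 0, between 0.21 and 0.63, with a median of 0.44 at percentile 99.5, and 2 passed 1.5-fold. Myh6, the adult myosin heavy chain (chromosome 14, 54941921 to 54968017), had 4461 against 3015 FPKM, and Ckm (0.63), the muscle creatine kinase, and Myl2 (0.59) were the highest. Cardiac stress and fetal genes differed among themselves, with a median of -0.41 at percentile 0.04. Nppa, the atrial natriuretic peptide (chromosome 4, 148000722 to 148002074), had 1565 against 4005 FPKM and Ankrd1 had -1.73, but Nppb, the B-type peptide, had 753 against 1011 FPKM. Acta1, the skeletal actin of the fetal heart, was higher (1.35), and the fetal myosin Myh7 had 278 against 196 FPKM. By the mean of members over all genes, cardiomyocyte genes lay at percentile 90.6 and cardiac stress genes at 6.74, and neither stood apart.

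Genes of mitochondrial energy production were higher together. All 20 genes of fatty acid uptake and oxidation lay above 0 and 15 were at least 1.5-fold higher, with a median of 0.61 above all random lists. They included Acot1 (1.29), a thioesterase, Ppargc1a (23.4 against 11.4 FPKM) and Ppara (0.95), regulators of mitochondrial and fatty acid genes, and Acadm (0.75), a dehydrogenase of medium-chain fatty acids. All 14 genes of the tricarboxylic acid cycle lay above 0, with a median of 0.57 and 5 past 1.5-fold, led by Idh2 (0.78) and Ogdh (0.78). All 23 nuclear-encoded genes of oxidative phosphorylation lay above 0, with a median of 0.47 at percentile 99.9, and 4 passed 1.5-fold, among them Uqcrfs1 (0.67) and Uqcrc1 (0.61). By the mean of members over all genes, none of these lists stood apart, with fatty acid genes at percentile 96.4, the tricarboxylic acid cycle at 92.7 and oxidative phosphorylation at 90.2. Genes of glycolysis went both ways around a median of 0.15, at percentile 53.5, with Eno1 at -0.94 and Ldhb at 0.69. Cardiac ion channels had a median of 0.19 within the range of random lists, although Kcnip2, a subunit of the transient outward potassium channel, had 1.22.

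For genes that a lipid-lowering antioxidant concerns, the picture was mixed. The antioxidant and Nrf2 target list had a median of -0.12 at percentile 1.55, with 4 of 20 members at least 1.5-fold lower and 0 higher. The 4 were Hmox1, the metallothionein Mt2 (-1.93) and the glutathione peroxidases Gpx1 (-0.74) and Gpx3 (-0.62), while Sod2 and Cat, chosen after their values were seen, had 0.54 and 0.53. Without matching on expression, this list lay at percentile 11.2. NADPH oxidase and other oxidant sources had a median of -0.91, with 6 of 11 lower, among them the phagocyte oxidase subunits Ncf1 (-1.65) and Cybb (-1.42). Targets of SREBP2, the regulator of cholesterol synthesis, had 0 of 14 members past 1.5-fold in either direction, with values between -0.53 and 0.49 and the median at percentile 67.6. Genes of cholesterol efflux and LXR targets had a median of -0.22 at percentile 0.78, with Pltp (-1.27), Arl4c (-0.87) and Abcg1 (-0.68) past 1.5-fold. This list of cholesterol efflux and LXR targets did not stand apart without matching (percentile 5.32), by its mean (4.48) or without its most influential member (median -0.09, percentile 6.40).

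Markers of other cells in the tissue were compared in the same way. Endothelial markers had a median of -0.01 (percentile 18.6), which rescaling to TPM took to -0.15, smooth muscle and pericyte markers had -0.08 (percentile 18.8), and lymphatic endothelial markers had 0.09 (percentile 77.7). Endothelial activation genes stood apart at -0.60, with Sele (-1.02), Selp (-0.88) and Ackr1 (-0.72) lowest. Erythroid genes were higher, with a median of 0.86 above all random lists and 6 of 7 past 1.5-fold, including Alas2 (1.36), the heme synthesis enzyme of red cells, and the globins Hbb-bs (1.05) and Hba-a1 (0.94), which have near-identical copies. Neutrophil markers went both ways, with a median of -0.79, 5 of 9 lower and 2 higher. Camp, of neutrophil granules, was listed at 0 with probucol and at 2.06 FPKM without, Ngp, of the same granules, had -1.54 and Retnlg had 0.88. The most abundant members, S100a8 (73.9 against 52.4 FPKM) and S100a9 (64.9 against 42.4), were higher with probucol. In sum, the 9 measured neutrophil markers had 146 against 107 FPKM, so the lower median rests on the less abundant members. Among neutrophil markers of at least 1 FPKM the median turned to 0.49. Mast cell markers had a median of -0.64 at percentile 2.48, a call that was lost under 11 alternatives, with percentiles from 2.67 to 14.0. Skeletal muscle genes (4 measured, median 0.54) stood apart as higher, and their values of 13.3 against 8.64 FPKM in sum were far below those of heart muscle genes. With no filter the skeletal muscle genes had a median of 0.15 at percentile 94.1 and did not stand apart.

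**Figure D3:**
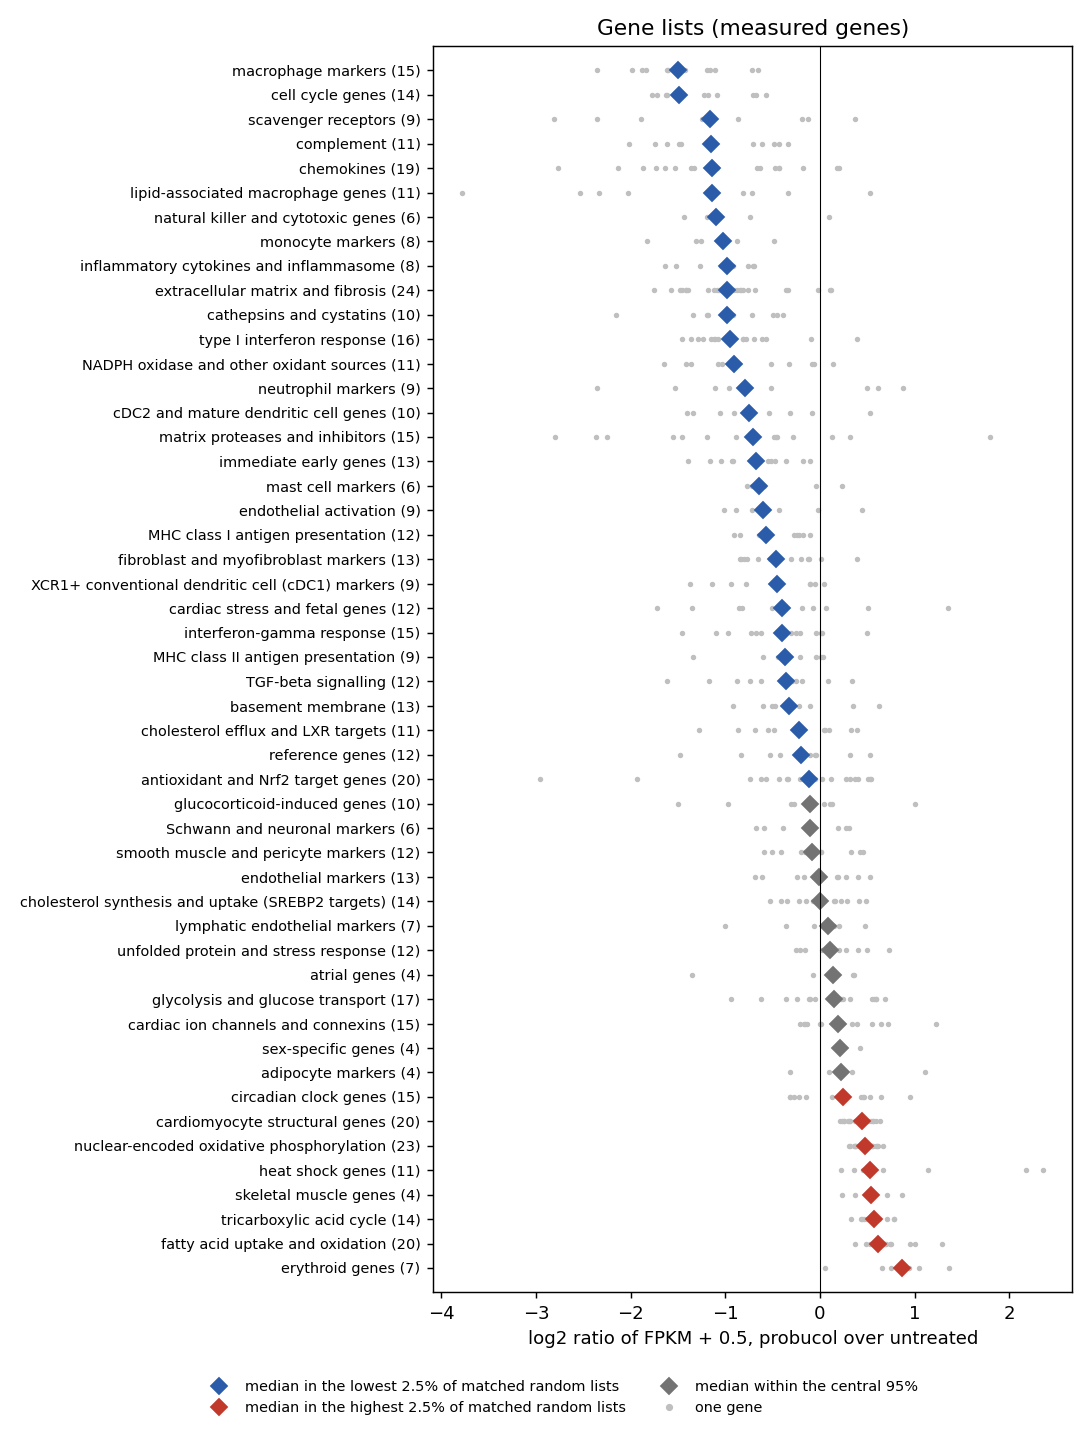
Median log2 ratio of each of the 50 lists with at least 4 measured members (diamonds; blue in the lowest and red in the highest 2.5% of matched random lists, dark grey between) and each member (light grey points), x axis as log2 ratio of FPKM + 0.5, probucol over untreated; the number of measured members stands in brackets. Macrophage markers (-1.50) and cell cycle genes (-1.49) lie at one end and erythroid genes (0.86) at the other.

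Several commonly used reference genes differed between the libraries. Their list had a median of -0.20 at percentile 1.32, with Gusb, a lysosomal enzyme, at -1.48 and Actb at -0.84 past 1.5-fold, whereas Gapdh had 0.32 and Sdha had 0.53. The reference genes did not stand apart without matching (percentile 5.81), by their mean (7.84) or without their most influential member (2.68). The genes on the Y chromosome that were measured, Ddx3y, Uty, Kdm5d and Eif2s3y, were expressed in both libraries, with a median of 0.21 (percentile 86.8).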

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

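Of the settings below, the restriction to protein-coding genes was chosen after the data were seen. No paired analysis was possible because each group has 1 library. The 38 lists that stood apart kept their direction under every alternative except neutrophil markers, whose median turned to 0.49 among genes of at least 1 FPKM and 0.55 among genes of at least 5 FPKM, since these filters left 5 and 2 members. Of the 38, 15 stood apart in every setting, among them the macrophage, matrix, chemokine, complement, interferon and erythroid lists, and 23 did not in at least 1. For 10 of the 23 the mean of members over all genes was the sole exception: cardiomyocyte genes then had 0.42 (percentile 90.6), oxidative phosphorylation 0.48 (90.2) and cardiac stress genes -0.37 (6.74). Against random lists of protein-coding genes these 10 stood apart by their mean too, so the percentiles of the mean depended on whether the random lists held genes that are not protein-coding. The cDC1 list did not stand apart with pseudocount 0.1 (-0.47), no filter (-0.31), at least 1 FPKM (-0.28), at least 5 FPKM (-0.46, 3 members), TPM (-0.51) or without its most influential member (-0.28). The class II list lost its place at 1 FPKM (-0.29), without its most influential member (-0.29) and by its mean among all genes and protein-coding genes (-0.37 in both). The antioxidant list lost it unmatched (-0.12), by its mean (-0.26) and without its most influential member (-0.052). Th1 genes, with 5 members past the filter once rescaled without the 50 most abundant genes, had -1.14 and stood apart. For the dendritic cell, class II and antioxidant lists the cause was not tested. The counts of genes higher and lower were 711 and 1541 at 1.5-fold and 48 and 176 at 3-fold. At 5 FPKM they were 52 and 291 by fewer genes tested. They were 230 and 994 when rescaled without the 50 most abundant genes. That scaling also raised all values against the fixed pseudocount and filter, with 13775 genes past the filter, and these effects were not separated. With pseudocount 0.1 the genes higher numbered 229. Under each other setting both counts stayed within 1.5 times, with more genes lower than higher throughout. Of 250 named genes, 0 of those past 2-fold reversed and 36 moved by over 1.5-fold in at least 1 setting, 23 of them short RNAs. Depth limits Xcr1 and the helper T cell genes, for which few fragments were recovered.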

Other observations

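All tests of explanations in this part were chosen after the result was seen, and the platelet list and the restriction to protein-coding genes were also added then.

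Stress and activity genes that the comparison above left aside differed between the libraries. Heat shock genes had a median log2 ratio of 0.53 at percentile 99.9, with 11 of 11 above 0 and 4 at least 1.5-fold higher in the probucol library, Hspa1b, Hspa1a, Hsph1 (1.14) and Hspb1 (0.66); by the mean of members over all genes the heat shock list lay at percentile 96.2 and did not stand apart. Immediate early genes, which respond to handling and ischemia within minutes, had a median of -0.68 with 13 of 13 below 0 and 7 past 1.5-fold, including Fos (-1.40), Egr1 (-1.16) and Egr2 (-1.05). Circadian clock genes stood apart with a median of 0.25 at percentile 99.2, although members went both ways, from Dbp at -0.32 to Cry1 at 0.95, and lay at percentile 95.3 among genes of at least 5 FPKM. Glucocorticoid-induced genes lay within the range of random lists, with Lcn2 at -1.50 and Zbtb16 higher, and so did genes of the unfolded protein response, with a median of 0.11 and Herpud1 at 0.73.

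Among families of genes that share the start of their symbol, 18 of 141 lay lower and 9 higher than random families. By chance 7.05 would be expected for independent genes, which members of a family are not. The lower families include Mir (27 measured, median -0.97), short RNAs whose values are uncertain. The interferon-inducible Ifi genes had a median of -1.16, the C-type lectins (Clec) -0.85, annexins (Anxa) -0.72 and collagens (Col) -0.72. Cytosolic ribosomal proteins of the Rpl and Rps families were slightly lower, with medians of -0.21 and -0.17, while mitochondrial ribosomal proteins of the Mrpl and Mrps families were higher, with 0.27 and 0.25. Peroxins (Pex, 0.25) and cytochrome c oxidase genes (Cox, 0.32) were also higher. Each of these directions held under all 4 other scalings.

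Markers of further cell types were few or lay within the range of random lists. Adipocyte markers had a median of 0.22 over 4 members, with Cfd at 1.11 and Fabp4 at -0.32, and Schwann and neuronal markers had -0.10 over 6 members. Atrial genes had 0.13 over 4 members, with Nppa at -1.36 and Myl4 at 0.36. Too few members were measured for a call among B cell (3, median -1.26), plasma cell (2, median -0.14), epicardial (3, median -0.40) and lung, liver and thymus genes (3, median 0.53). Mitochondrially encoded genes were not analysed here.

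The joint pattern of lower macrophage, matrix and cell cycle genes with higher cardiomyocyte genes was weighed against the makeup of the tissue. A larger share of cardiomyocytes, diluting all other cells alike, would lower endothelial markers as much as macrophage markers. The macrophage median lay below the endothelial median by -1.49 (95% bootstrap interval over members -1.80 to -1.13). In these libraries this argues against such a dilution as the whole cause. The interval treats correlated genes as independent and says nothing of other animals. Fewer inflammatory cells, or less scar, in the piece of heart sampled remains open, since the matrix median of -0.98 is what either a smaller infarct in the sampled piece or the treatment would give. A difference by treatment, between single animals or between pieces cannot be told apart with 1 library per group.

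Platelet and red cell genes among the highest raised the question of more blood in the probucol sample. A list of 14 platelet genes was written after Gp9, Nrgn and Ppbp had been seen and was tested without these 3. Of the others, 7 were measured, with a median of -0.14 at percentile 35.7, 3 at least 1.5-fold higher and 1 lower. Of these, Itga2b (80 against 12 fragments) and Tubb1 (16 against 4) were higher. Gp6 (18 against 0, with a ratio of at least 4.90) and Gp5 (9 against 0) were higher too, but lay under the filter and outside the median. Pf4, which macrophages also express, had -1.04 and Gp1ba had -0.18. The platelet median lay -1.01 from the erythroid median, with an interval of -1.24 to 0.68. By these medians, more whole blood of the same makeup may be a source of these transcripts and was neither shown nor excluded. Itga2b and Gp6 were higher by more than the highest measured erythroid gene, Alas2 (2.58-fold), while Pf4 and Gp1ba were not higher. The most abundant erythroid gene, Hbb-b1, had 5098 against 3240 FPKM, which is 1 globin among near-identical copies.

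Short RNAs at the extremes are a candidate artifact of the unit. Of 32 genes under 200 bases, 71.9% were listed at 0 in 1 library although their mean FPKM passed the filter, against 0.269% of 12258 longer genes, a ratio of 267. Those shares include the extremes that raised the question. Without the 24 genes of the extremes, 4 of 13 short genes (30.8%) and 30 of 12254 longer genes (0.245%) were listed so, a ratio of 126 with an interval of 37.1 to 251. The filter itself favours such a ratio, since a longer gene at 0 in 1 library needs more fragments in the other to pass. The ratio therefore cannot decide on the cause. An effective length near 0, at which few fragments decide between 0 and a very high value, may be the cause, but losses of short RNAs in library preparation were not tested and remain open.

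Dendritic cell and macrophage genes offer a comparison within the same libraries. The cDC1 median lay 1.04 above the macrophage median (interval 0.353 to 1.503), so cDC1 transcripts may have been retained relative to macrophage transcripts. This stays open, because several of the 9 genes are expressed in other cells, which would hold up the median if immune cells were fewer. For Xcr1 the ratio lay between 0.269 and 1.52, a range that includes 0.355, the ratio of the macrophage median. A further hypothesis, that genes of lipid-associated macrophages were lower beyond macrophage markers as a whole, was neither shown nor excluded, since the medians differed by 0.36 with an interval of -0.85 to 0.80. Spp1, Trem2 and Gpnmb lay below the macrophage median and Ctsd (-0.72), Cd9 (-0.33) and Lpl above it.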
